A study of Mus musculus with 7 samples.

How the data were processed

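Mouse embryonic fibroblasts (MEFs) were profiled on the Affymetrix Clariom S mouse array, a 1-colour array that measures transcripts of annotated genes. Per the labels, fibroblasts received retroviruses for Gata4 and Tbx5 (GT) together with 1 form of Mef2c. The forms were isoform 1 (GT/M1), isoform 2 (GT/M2), isoform 6 (GT/M6) and isoform 2 joined to the transactivation domain of MyoD (GT/M2TAD). Fibroblasts without treatment gave the MEF array. No array carried virus without the factors. A further pair of arrays carried small interfering RNA (siRNA) against Ep300, the gene for the acetyltransferase p300, or a control siRNA, and are called siEp300 and siCtrl. Per the labels' protocols, medium was replaced 24 h after infection and transduced cells were harvested at 1 week. No time of harvest was given for the MEF array. RNA had an integrity number above 7, and 100 ng entered labelling. The 7 arrays formed 7 groups of 1 array each.

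The deposited values were log2 signals. Per the submitters' processing notes they came from Affymetrix Expression Console 1.4, and the series text names the SST-RMA method. Its settings were not given in the sources used here. Signals near the background of an array understate differences in transcript, and normalization across arrays can hide a shift shared by most genes. No genome build was given in the sources used here, so no positions are reported. The RefSeq gene table of the GRCm38.p6 assembly was used only for names.

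The table held 28846 probe sets. Of these, 19572 had 1 gene symbol in the platform annotation and none had several, and all 19572 matched the gene table by Entrez identifier with 0 symbols changed. They covered 19505 genes. For the 55 genes with several probe sets, the set with the highest mean over the 7 arrays was used. The 9274 probe sets without a symbol were 5222 negative-control probes, 1324 positive-control probes, 94 background, spike-in or ERCC sets and 2634 unnamed transcript sets. They entered no gene count, gene list or named gene, and were used only to gauge background and array shifts and for the counts in the closing section.

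Precision was limited by the number of arrays. With 1 array per group there was no estimate of spread between replicates, no test of it and no p-value, and no difference here has a replicate check. Genes were therefore counted by a fixed rule of size. A gene counted as 2-fold apart when its log2 difference was at least 1 in either direction and its higher value reached that array's median over named genes. The 95th percentile of the negative-control probes lay between 8.43 and 9.33 on the log2 scale, and 23.7% to 29.6% of genes lay above it. Among negative-control probes at or above the same floor, 26.8% to 54.2% were 2-fold apart in the 12 comparisons, so single genes of low signal carry little weight. Where 1 of 2 signals lay near background, the size of the difference rests in part on it.

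Gene lists were fixed before the data were examined. The 19 lists held 486 genes, of which 455 were measured and 31 were not named in the probe table. They covered the cardiac sarcomere, calcium handling and ion channels, cardiac transcription factors, cardiac hormones and stress genes, cardiac metabolism, skeletal muscle, smooth muscle and myofibroblast genes, fibroblast and matrix genes, TGF-beta targets, cell cycle, interferon response, inflammatory cytokines, p53 and stress genes, and acetyltransferases and deacetylases. Lists for other cell types covered macrophage, endothelial, epithelial and mesothelial, neural, and adipocyte and chondrocyte genes. For each list the median log2 difference was set against 10000 random lists of the same size, matched on mean signal in 20 bins. A list is called above or below when its median lay beyond the 97.5th or under the 2.5th percentile of those lists, and within otherwise. These percentiles describe the arrays and are not tests. In data simulated for the siEp300 and siCtrl comparison over 19505 genes, 7% of random lists were called above or below. The simulation started from the GT/M2 array and gave each gene its own noise. Its 7% therefore does not cover lists whose genes vary together.

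The named genes were, for each comparison, the 10 highest and 10 lowest log2 differences among genes that reached the floor, without predicted genes, plus the transduced factors, Myod1 and Ep300 on every array, plus list members 2-fold apart or with the largest differences. The report describes 12 comparisons between pairs of arrays. Alternatives also set siEp300 against GT/M2TAD and GT/M2, and counts over all 6 transduced arrays set it against MEF. The comparisons with the MEF array share that array, so no correlation between them is given, and the closing section's counts over all 6 are not independent evidence. Whether genes 2-fold apart between GT/M2TAD and GT/M2 differed with Ep300 siRNA was asked on arrays that share none with the choice of genes, against 10000 matched random sets. In data simulated for GT/M2TAD and GT/M2 over 19505 genes, 98% and 100% of genes set 1.5 higher or lower were recovered. Both simulations assumed noise of 0.2 on the log2 scale. Differences of negative-control probes spread more widely, with an SD of 1.06 between GT/M2TAD and GT/M2 and 1.24 between siEp300 and siCtrl. Both simulated rates hold only for noise of 0.2.

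Alternatives fixed before the data were examined were other fold thresholds, other floors, quantile normalization, median centring of arrays, the mean of a gene's probe sets, the mean of a list, unmatched random lists and other comparator arrays. Chosen after seeing the data were level-dependent centring (each difference minus its running median over 1001 genes of neighbouring signal), a floor at the 95th percentile of the negative-control probes, and the mean of the GT/M1, GT/M2 and GT/M6 arrays as comparator for GT/M2TAD. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.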

Results

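The series addressed how the form of Mef2c, given to fibroblasts together with Gata4 and Tbx5, shapes gene expression during direct reprogramming towards cardiac muscle, and what part p300 has in it. The 7 arrays covered untreated MEFs, the siCtrl and siEp300 cells and the 4 Mef2c forms without siRNA, with 1 array each. There were no replicates, so all differences below are between single arrays. Median signals over 19505 genes lay between 5.38 and 5.71 on the log2 scale. All differences are log2 differences between the arrays named.

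The transduced factors were examined first. Tbx5 had a signal of 5.72 on the MEF array, between 16.14 and 16.23 on the 4 arrays without siRNA, and 14.83 and 14.82 on siCtrl and siEp300. Mef2c had a signal of 8.24 on the MEF array and between 18.32 and 18.87 on the 6 transduced arrays. Gata4 stayed between 3.57 and 5.09 on every array, including 4.22 on MEF. Myod1, the source of the fused domain, lay between 2.94 and 3.54 on all arrays. Ep300 was 9.47 on siEp300 and 9.90 on siCtrl, a difference of -0.43, and between 9.87 and 10.22 on the other arrays. Where the probes lie relative to the transduced coding sequences and the siRNA target is not known, so the Gata4, Myod1 and Ep300 values check the labels only in part. The labels of the siRNA samples disagree: their titles name GT/M2, and their source names and characteristics name GT/M2TAD. These arrays are therefore called only siCtrl and siEp300.

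Each Mef2c form was compared with untreated MEFs to ask how far the fibroblasts took up cardiac gene expression. The MEF array was not infected and its time of harvest is not known. Differences from it therefore cannot tell the factors apart from infection or time in culture. On GT/M2TAD, Nppa, which encodes atrial natriuretic peptide, was 13.43 higher than on the MEF array. Csrp3, a muscle LIM protein of the Z-disc, was 12.96 higher, the glycogen-targeting phosphatase subunit Ppp1r3c 13.05 higher and the atrial myosin light chain Myl4 11.35 higher. Gpx3, the desmosomal gene Dsp, Pdlim3 and Serpina3n were 11.82, 11.76, 11.42 and 10.65 higher. Among the lowest genes were Crabp1, a binding protein for retinoic acid, at -8.41, Bcat1 at -7.95, Tm4sf1 at -7.80, the protease Tll1 at -7.68, Adam12 at -7.37, Dlk1 at -7.23 and F3, which encodes tissue factor, at -7.23. On GT/M1, GT/M2 and GT/M6 the atrial light chain Myl7 was 12.87, 12.34 and 13.02 higher than on MEF, and Ptgs2, which encodes cyclooxygenase-2, was among the lowest genes, at -8.66, -9.37 and -8.12. Each gene named in this paragraph had 1 of its signals below the 95th percentile of the negative-control probes, so the size of its difference and its rank rest in part on background.

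Genes of the cardiac sarcomere formed a group that was higher with every Mef2c form. Of 34 measured members, 20 were at least 2-fold higher on GT/M1, 20 on GT/M2, 21 on GT/M6 and 24 on GT/M2TAD. The list medians were 2.53, 4.0, 2.90 and 3.44, all above the matched random lists. Tnnt2, cardiac troponin T, was 9.79, 9.21, 9.77 and 10.06 higher. Members at least 2-fold lower were Tpm1 on GT/M1 at -1.17, on GT/M2 at -1.25 and on GT/M6 at -1.08, and Pdlim5 on GT/M6 at -1.06. The calcium handling and ion channel list had medians of 1.04, 0.64, 1.09 and 0.79, again above the random lists. The ryanodine receptor Ryr2 was 8.54, 7.24, 8.13 and 6.77 higher, and the sarcoplasmic calcium-binding protein Casq2 8.02, 7.68, 9.78 and 9.41 higher. The gap junction gene Gjc1 was lower with all 4 forms, at -3.28, -3.00, -2.85 and -2.95. Cardiac hormone and stress genes had medians of 2.66, 2.87, 2.5 and 3.33, and cardiac metabolism genes 1.00, 1.21, 1.19 and 0.67, all above. Fabp3, a fatty acid binding protein of heart muscle, was 8.92, 9.28, 8.59 and 8.76 higher. Among 24 cardiac transcription factors, Tbx20 was 7.25, 5.92, 5.81 and 2.84 higher and Foxp1 lower at -3.67, -3.48, -3.44 and -3.13. That list's medians were -0.25, -0.12, -0.070 and -0.017, below the random lists on GT/M1 and within them on the others.

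**Figure D1:**
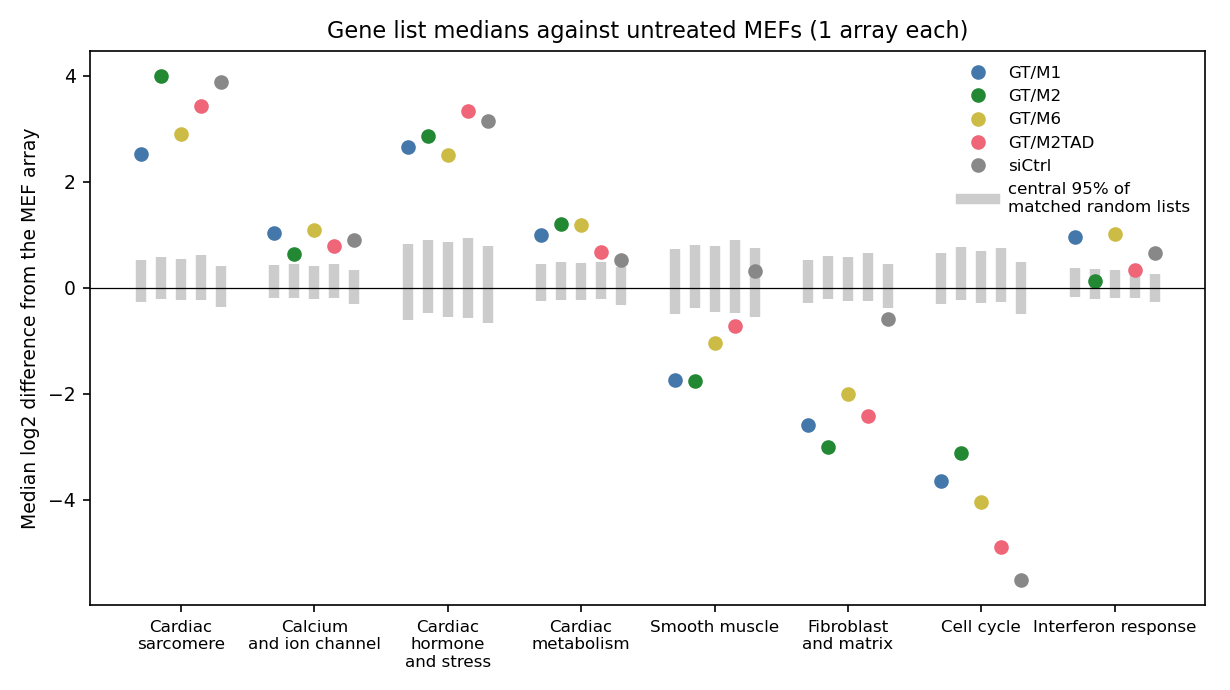
Each point is the median log2 difference of a gene list from the untreated MEF array (vertical axis) for 1 transduced array, and grey bars span the central 95% of 10000 expression-matched random lists. Cardiac sarcomere medians lie between 2.53 and 4.0, and cell cycle medians between -5.52 and -3.11.

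Cell cycle and matrix genes were lower on the same arrays. All 29 measured cell cycle genes were at least 2-fold lower with each form, with list medians of -3.65, -3.11, -4.04 and -4.90 in the same order. Mki67, a proliferation marker, was at -4.39, -3.49, -4.43 and -6.29, and the ribonucleotide reductase subunit Rrm2 at -5.43, -5.38, -5.85 and -6.96. Fibroblast and matrix genes had medians of -2.60, -3.00, -2.0 and -2.43, and 28, 30, 26 and 28 of 36 members were at least 2-fold lower. Col6a3, a collagen VI chain, was at -6.55, -7.15, -5.78 and -6.30. Dcn, which encodes the proteoglycan decorin, went the other way on GT/M1, GT/M2 and GT/M6, at 6.70, 4.98 and 5.73 higher. Smooth muscle and myofibroblast genes had medians of -1.74, -1.76, -1.04 and -0.71, below the random lists, with the calponin gene Cnn1 at -5.21, -6.24, -5.44 and -4.24.

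Lists of other pathways and cell types were read in the same way. For GT/M2TAD against MEF, TGF-beta targets had a median of -0.78, inflammatory cytokines -0.59, macrophage genes -0.59 and endothelial genes -0.27, all below the random lists. The macrophage call was lost with the mean, at percentile 9.08. The endothelial call was lost with the mean, unmatched lists, quantile normalization and level-dependent centring, at percentiles 2.99, 4.04, 2.66 and 2.58. Ccl2, a monocyte chemokine, was at -6.53. Interferon response genes at 0.34, skeletal muscle genes at 0.031, p53 and stress genes at 0.064, acetyltransferases and deacetylases at -0.35, epithelial and mesothelial genes at -0.0034, neural genes at -0.18 and adipocyte and chondrocyte genes at -0.23 were within the random lists. Some of these lists left the random lists under an alternative. Interferon genes were above with the mean (0.63), epithelial and mesothelial genes with the mean (0.65) and over members at the floor (2.02). Neural genes were below with the mean (-0.80) and over members at the floor (-1.29), and acetyltransferases and deacetylases against unmatched lists. The skeletal and p53 medians were -0.23 and -0.20 after median centring, which shifts all genes alike. Both stayed within the random lists, at unchanged percentiles of 44.03 and 28.66. On GT/M1 and GT/M6, interferon response genes had medians of 0.96 and 1.02, above the random lists. Skeletal muscle genes were within the random lists on all 4 arrays, with 2 of 34 at least 2-fold higher on GT/M2TAD, the light chain Myl1 at 5.71 and the acetylcholine receptor subunit Chrnb1 at 1.74.

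By the rule of size, 2437 genes were higher and 1856 lower on GT/M1 than on MEF, 2643 and 1626 on GT/M2, 2545 and 1715 on GT/M6, and 2729 and 1853 on GT/M2TAD. The split depended on scaling: median centring, which shifted the median of all genes from 0.089, 0.072, 0.077 and 0.091 to -0.22, -0.25, -0.25 and -0.17, gave 1815 and 2513, 1955 and 2222, 1852 and 2444, and 2158 and 2387. Quantile normalization gave 1976 and 2233, 2146 and 1954, 2078 and 2114, and 2227 and 2228.

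The Mef2c isoforms were compared with each other to ask whether they differ in the genes that are higher or lower with them. Between GT/M2 and GT/M1, the highest gene on GT/M2 was Myoz2, a Z-disc gene, at 5.18. Csrp3 was 4.02 higher, the fast light chain Myl1 3.36 higher and Synpo2l, a Z-disc protein gene, 3.20 higher. Among the lowest genes were Sln, which encodes the calcium pump regulator sarcolipin, at -5.98, the hormone gene Cck at -5.54, the atrial connexin Gja5 at -2.61 and Bmp2 at -2.69. The sarcomere list median was 0.34 and that of the cell cycle list 0.71, both above the random lists. Calcium and ion channel genes at -0.31, matrix genes at -0.49 and interferon response genes at -0.74 were below, with 10 of 33 interferon genes at least 2-fold lower. Macrophage genes were below as well, at a median of -0.51, with 5 of 18 at least 2-fold lower: Lyz2, Mrc1, Cd14, Laptm5 and Mpeg1. The signals of these 5 genes, Gja5 and Bmp2 lay below the 95th percentile of the negative-control probes on both arrays. In all, 370 genes were higher and 271 lower on GT/M2, and 289 and 346 after level-dependent centring.

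GT/M6 differed from GT/M1 by fewer genes, 126 higher and 57 lower. The potassium channel gene Kcnj3 was 4.01 higher, Myoz2 2.07 higher and the interferon-induced genes Ifit1, Ifit3b and Ifit3 2.35, 2.29 and 2.19 higher. Nppa was at -1.89, Tbx20 at -1.43, Bmp2 at -2.06 and the neurokinin receptor gene Tacr1 at -3.02. The signals of Kcnj3, Ifit1, Ifit3b, Bmp2 and Tacr1 lay below the 95th percentile of the negative-control probes on both arrays. Interferon response genes had a median of 0.34 and matrix genes 0.40, both above the random lists, while macrophage genes at -0.47 were below and the sarcomere median of 0.12 was within them and the mean of 0.36 above. Against GT/M2, 360 genes were higher on GT/M6 and 334 lower. Sln was 5.43 higher, Cck 5.03, Kcnj3 4.32, Ifit3b 4.10 and Gja5 3.34. Myoz2 was at -3.11, the actin-binding gene Lmod2 at -2.96, Synpo2l at -2.49 and Krt19 at -3.65, with Kcnj3, Ifit3b and Lmod2 below that percentile on both arrays. Matrix genes had a median of 0.99 with 18 of 36 at least 2-fold higher, and interferon response genes 1.13 with 14 of 33 higher. Neural genes at 0.39, smooth muscle genes at 0.67 and TGF-beta targets at 0.59 were above. Calcium and ion channel genes at 0.27 and cardiac transcription factors at 0.21 were above too. The transcription factor call was lost over members at the floor, at percentile 68.35. Cell cycle genes at a median of -0.91, cardiac metabolism genes at -0.47 and hormone and stress genes at -0.46 were below the random lists, and the hormone call was lost with the mean, at percentile 3.59. The sarcomere median was -0.055, within the random lists, and the mean of -0.28 lay below them.

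GT/M2TAD was compared with GT/M2 to ask how expression differed when the same isoform carried the MyoD domain. Smooth muscle genes were higher as a group, with a median of 1.28 and 12 of 18 members at least 2-fold higher and 0 lower. Lmod1 was 2.37 higher, the tropomyosin gene Tpm2 2.30, smooth muscle myosin Myh11 2.07, Actg2 2.03 and Cnn1 1.99. Cell cycle genes were lower, with a median of -1.73 and 22 of 29 at least 2-fold lower, among them Tpx2 at -3.09, the mitotic kinase Plk1 at -3.07 and Mki67 at -2.80. On GT/M6 against GT/M2, both without the domain, the smooth muscle and cell cycle medians were 0.67 and -0.91. Part of both differences may thus rest on the GT/M2 array. The signals of Lmod1, Myh11 and Tpx2 lay below the 95th percentile of the negative-control probes on both GT/M2TAD and GT/M2. The genes furthest apart were the chemokine Ccl17, the nuclear receptor Nr4a3 and the receptor component Ramp1, 5.24, 5.19 and 4.79 higher. At the other end stood Cbln2 at -5.86, Corin, the protease that processes atrial natriuretic peptide, at -4.45, Dcn at -4.38 and Igfbp5 at -4.14.

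Sarcomere genes went both ways between these arrays. The list median was 0.47, above the random lists, with 9 of 34 members at least 2-fold higher and 7 lower. With siCtrl in place of GT/M2TAD the median was 0.0076, within the random lists. Higher were Xirp2 at 3.66, Synpo2l at 2.42, the M-band gene Myom1 at 2.33, Smpx at 1.86, Xirp1 at 1.54, Ldb3 at 1.38, Nexn at 1.21, Pdlim5 and Actn2. Lower were the cardiac myosin heavy chains Myh6 at -2.57 and Myh7 at -1.72, cardiac troponin I, Tnni3, at -2.38, Myl7 at -2.34, Myoz2 at -1.21, Myom2 at -1.19 and titin, Ttn, at -1.15. On both arrays, the signals of Myom1, Xirp1, Tnni3, Myh7, Hcn4, Hey2 and Tbx3 lay below the 95th percentile of the negative-control probes. Cardiac hormone and stress genes had a median of 0.91, above, with Nppa 2.43 and Nppb, which encodes the B-type peptide, 2.39 higher. Calcium and ion channel genes had a median of 0.066, within the random lists, with Sln 2.57 higher and the pacemaker channel gene Hcn4 at -3.24. Of the cardiac transcription factors, Tbx20 at -3.08, Tbx2 at -1.70, Hey2 at -1.69, Tbx3 at -1.15 and Meis1 at -1.06 were at least 2-fold lower. The median of their list was 0.13, within. Matrix genes had a median of 0.42, above, with Thy1 3.34 and Timp1 2.79 higher. Cardiac metabolism genes had a median of -0.24, below, and interferon response genes 0.27, above.

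**Figure D2:**
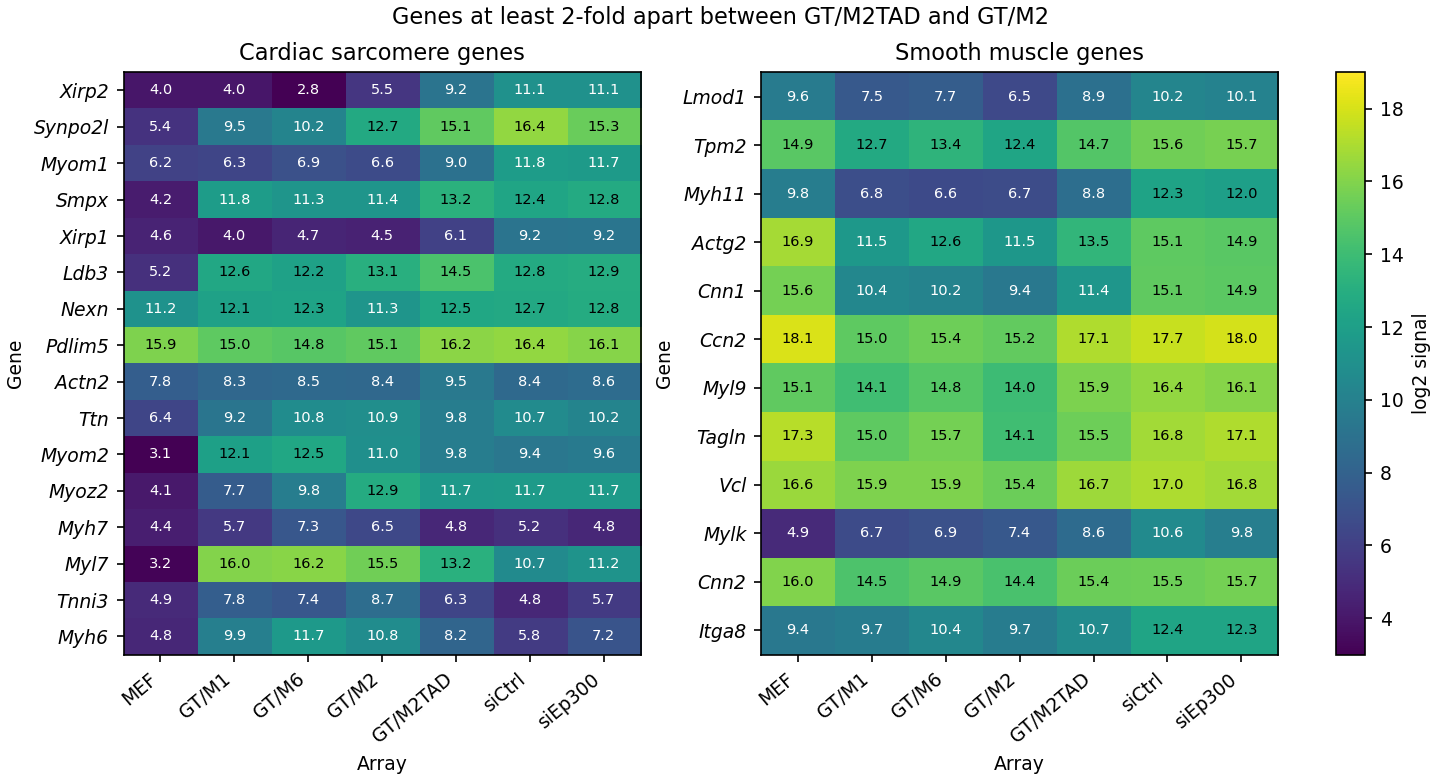
Colour and printed numbers give the log2 signal of each gene (vertical axis) on each array (horizontal axis), for cardiac sarcomere genes (left) and smooth muscle genes (right) at least 2-fold apart between GT/M2TAD and GT/M2. Myh6 has a signal of 10.78 on GT/M2 and 8.21 on GT/M2TAD, and Xirp2 5.50 and 9.17.

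In all, 578 genes were higher on GT/M2TAD and 650 lower, against 654 and 578 after median centring and 622 and 598 after level-dependent centring. Against the mean of the GT/M1, GT/M2 and GT/M6 arrays, a comparator chosen after seeing the data, the matrix median was -0.016, the metabolism median -0.0016 and the interferon median -0.35, so those calls rest on GT/M2 as comparator. The smooth muscle, cell cycle, sarcomere and hormone calls held.

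siEp300 was compared with siCtrl to ask which genes differ with Ep300 siRNA. Interferon response genes were higher on siEp300, with a median of 0.64 and 8 of 33 members at least 2-fold higher, among them Ifit1 at 2.31, Ifit3b at 1.77, Ifit3 at 1.58 and Usp18 at 1.48. Arrays without siRNA differed more on this list, by 1.13 for GT/M6 against GT/M2 and -0.74 for GT/M2 against GT/M1. Cell cycle genes were higher too, with a median of 0.52, and 3 of 29 at least 2-fold higher: the ubiquitin ligase gene Ube2c at 1.30, cyclin A2, Ccna2, at 1.17 and Plk1 at 1.05. Smooth muscle genes had a median of -0.19 and matrix genes -0.024, both below the random lists, with 0 members at least 2-fold apart. The cell cycle, smooth muscle and matrix calls rest on siCtrl as comparator. Against GT/M2TAD and GT/M2, cell cycle medians were -0.44 and -2.37, below, smooth muscle medians 0.96 and 2.52 and matrix medians 1.66 and 1.91, above. Among single genes, Depdc7 was 2.44 higher, the endothelial growth factor receptor gene Kdr 2.16 and Nppb 2.13, while the embryonic myosin heavy chain Myh3 was at -2.55 and the dyskerin gene Dkc1 at -1.78. The signals of Ifit1, Ifit3, Ifit3b, Ube2c, Ccna2, Plk1, Depdc7, Kdr, Myh3 and Dkc1 lay below the 95th percentile of the negative-control probes on both arrays, and those of Usp18 above it. Plk1 fell below 2-fold after quantile normalization, median centring and level-dependent centring, and Ccna2 after the first and last of these.

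The median of all genes was 0.14 higher on siEp300 than on siCtrl, and list medians are read against the random lists, which carry the same shift. Cardiac sarcomere genes had a median of 0.20, within the random lists, with Myh6 1.34 higher and Synpo2l at -1.05. Cardiac transcription factors had a median of -0.13 and calcium and ion channel genes -0.041, both below. Cardiac hormone and stress genes at -0.053 and cardiac metabolism genes at 0.079 were within, with the pyruvate dehydrogenase kinase gene Pdk4 at 1.37, Mb at 1.04 and Cox7a1 at 1.01. The signals of Myh6, Mb and Cox7a1 were below that percentile of the negative-control probes on both arrays, and Mb and Cox7a1 fell below 2-fold after quantile normalization, median centring and level-dependent centring. After median centring, which shifts all genes alike, the metabolism median was -0.086 at an unchanged percentile of 23.22. By the rule of size, 377 genes were higher on siEp300 and 76 lower. That split depended on scaling: quantile normalization gave 160 higher and 164 lower, median centring 195 and 141, and level-dependent centring 159 and 154. The calcium and ion channel call was lost under quantile normalization, where its median of -0.17 lay at percentile 2.86, and also with the mean, unmatched random lists and level-dependent centring. The cell cycle call was lost among members at or above the floor, at a median of 0.31 and percentile 83.1, and the matrix call with unmatched random lists, at percentile 3.60. The transcription factor call was lost with the mean, at 0.0076 and percentile 7.34, and with GT/M2 as comparator, at percentile 37.9.

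Genes at least 2-fold apart between GT/M2TAD and GT/M2 were then followed under Ep300 siRNA. They rest on 1 array each, and the GT/M6 and GT/M2 arrays, both without the MyoD domain, were 694 genes apart. Over the 578 genes higher on GT/M2TAD than on GT/M2, such as Ccl17 and Nr4a3, the median difference between siEp300 and siCtrl was 0.081. Matched random sets had medians between 0.14 and 0.22 in their central 95%, so the set lay below them. Over the 650 genes lower on GT/M2TAD, such as Tbx20 and Myh6, the median was 0.31, against 0.16 to 0.23 in the random sets. The 650 genes held 22 of the 29 cell cycle genes, a list 0.52 higher on siEp300 than on siCtrl. After level-dependent centring the medians were -0.098 and 0.12, below and above the random sets. Of the 578 genes, 14 were at least 2-fold higher on siEp300 and 4 at least 2-fold lower. Of the 650 genes, 52 were higher and 7 lower. These counts carry the shift of all genes: after level-dependent centring they were 10 and 10, and 23 and 12. The 2729 genes higher on GT/M2TAD than on MEF had a median of 0.23, above the random sets, and the 1853 lower ones 0.16, within.

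**Figure D3:**
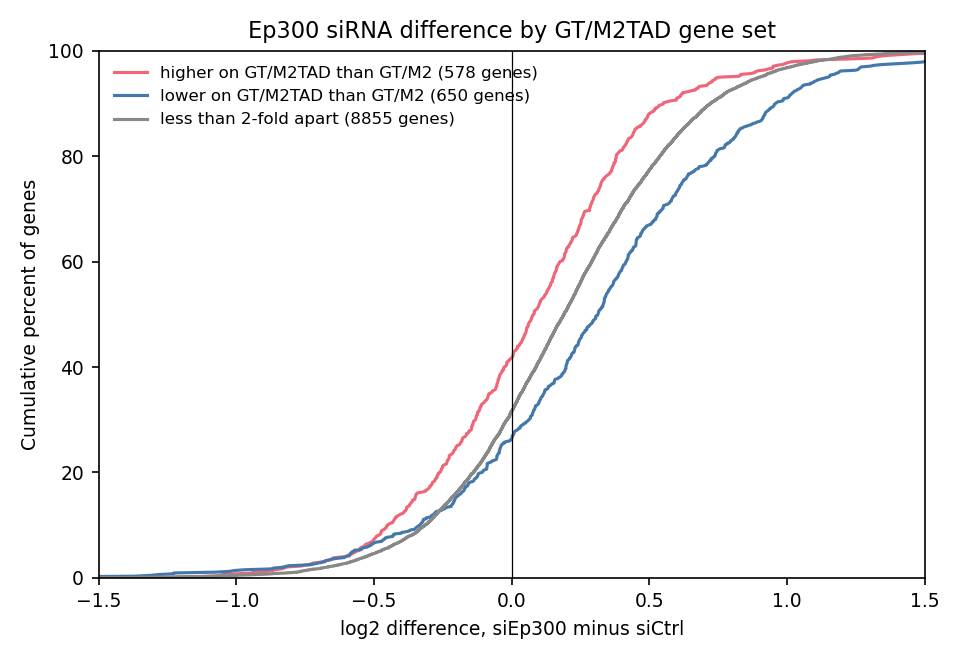
Cumulative percent of genes (vertical axis) by the log2 difference of siEp300 minus siCtrl (horizontal axis) for genes higher, lower or less than 2-fold apart between GT/M2TAD and GT/M2. The curve of the 578 higher genes, with a median of 0.081, lies left of the curve of the 650 lower genes, with a median of 0.31.

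Because the labels disagree on the construct of the siRNA samples, siCtrl was compared with both candidates. Matrix genes were higher on siCtrl than on GT/M2TAD, with a median of 1.78 and 22 of 36 at least 2-fold higher, and the small matrix proteoglycans Aspn and Ogn were 8.25 and 5.51 higher and periostin, Postn, 5.09 higher. Smooth muscle genes had a median of 0.91 and skeletal muscle genes 0.16, both above the random lists, with 9 of 34 skeletal genes at least 2-fold higher, among them Casq1 at 3.35 and the fast troponin T gene Tnnt3 at 3.22. Interferon response genes at 0.42, macrophage genes at 0.43 and inflammatory cytokines at 0.31 were above as well. Cell cycle genes had a median of -0.95, below. The retinal cadherin gene Cdhr1 was at -6.03, Ppp1r3c at -4.39, Ryr2 at -3.10 and Myl7 at -2.49. Against GT/M2, siCtrl had a matrix median of 1.99, a smooth muscle median of 2.60, a cell cycle median of -2.77 and a cardiac metabolism median of -0.84. Myh6 was at -4.97, Myl7 at -4.83, Tbx20 at -5.72 and Xirp2 5.58 higher. By the rule of size, siCtrl had 592 genes higher and 1245 lower than GT/M2TAD, and 1033 higher and 2177 lower than GT/M2. The median of all genes was -0.14 and -0.12 in these comparisons, and median centring gave 808 and 826, and 1451 and 1458. The majority turned after quantile normalization, to 921 and 678, and 1480 and 1388, and after level-dependent centring, to 893 and 705, and 1522 and 1362. Against MEF, siCtrl had 2127 genes higher and 2118 lower, a sarcomere median of 3.88 and a cell cycle median of -5.52.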

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

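Both counts given here were chosen after the data had been seen, and no explanation was tested for either. They stood out because they come from probes that the comparisons do not use. Of 2634 transcript probe sets with no gene symbol, 83 were at least 2-fold higher on each of the 6 transduced arrays than on the MEF array, and 81 were at least 2-fold lower on each of them. Among 19505 genes the same counts were 1225 and 924, and among 5222 negative-control probes 28 and 54. The comparison shares 1 MEF array, so a low or high value on that array alone enters all 6 differences.

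A further 32 negative-control probes, 0.613% of them, had signals at or above the 95th percentile of genes on every array. No biological explanation was tested.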

How the results depend on the processing

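Level-dependent centring, the floor at the 95th percentile of negative-control probes and the mean comparator for GT/M2TAD were chosen after the data had been seen, and the other alternatives before. Of 111 alternative counts, 63 stayed within 1.5 times the value reported and 48 did not. Of 860 alternative list values, 790 kept their call, 21 lost it, 38 gained one and 11 fell on the other side of the random lists' median. Median centring shifts a list and its random lists alike, so it could not change a call. The mean of probe sets could alter only the 55 genes with several probe sets. The 790 therefore include values whose call was fixed in advance. Single genes were run under quantile normalization, median centring, the mean of probe sets and level-dependent centring. These were the 10 highest and 10 lowest genes of each comparison, list members 2-fold apart, and Ep300, Mef2c and Tbx5 for siEp300. Of 7192 values from 1798 differences, 6976 kept their direction and their side of 2-fold, and 216 kept their direction but fell below 2-fold. Most of these genes were chosen for large differences on the same arrays, so their direction could hardly change. Of 26 alternatives for the genes followed under Ep300 siRNA, 22 kept their call and 4 gained one. No paired analysis was possible because each group had 1 array. Leaving out an array was not possible for the same reason. Signal over background limits what can be read, since 23.7% to 29.6% of genes exceeded the 95th percentile of negative-control probes.

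A stricter or looser rule changes counts by its construction. Against MEF, a 3-fold rule gave 2419 genes for GT/M1, 2495 for GT/M2, 2406 for GT/M6, 2688 for GT/M2TAD and 2452 for siCtrl, and a 1.5-fold rule gave 6384 for siCtrl. A floor at the 75th percentile gave 2556, 2446, 2544, 2789 and 2608 in that order, and the negative-probe floor 2526, 2665, 2609, 2877 and 2798. For GT/M2 against GT/M1, 1.5-fold gave 2172, 3-fold 178, the 75th percentile floor 295 and the negative-probe floor 316. For GT/M6 against GT/M1 these were 922, 37, 74 and 73, and 355 with no floor. For GT/M6 against GT/M2 they were 2061, 211, 326 and 354, and for GT/M2TAD against GT/M2 they were 3149, 405, 696 and 746. For siEp300 against siCtrl they were 2157, 44, 84 and 123, and 1078 with no floor. In place of siCtrl, the GT/M2TAD array gave 1402 genes and the GT/M2 array 2611.

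The causes of the following were not tested. With the mean in place of the median, the sarcomere value was 0.36 for GT/M6 against GT/M1 and -0.28 against GT/M2, both then outside the random lists. With siCtrl in place of GT/M2TAD, the sarcomere median against GT/M2 was 0.0076, within them. With the mean of GT/M1, GT/M2 and GT/M6 as comparator for GT/M2TAD, the metabolism median was -0.0016 and the matrix median -0.016. Both were then within the random lists, at percentiles 51.42 and 39.02. The interferon median was -0.35, beyond the random lists on the other side. For siEp300, the calcium and ion channel call was lost with the mean (0.019), unmatched lists (-0.041), quantile normalization (-0.17) and level-dependent centring (-0.17). It was also lost with GT/M2 as comparator (-0.036) and with GT/M2TAD as comparator (0.0048, percentile 59.12). The matrix call was lost with unmatched lists (-0.024) and the cell cycle call with the floor (0.31). With GT/M2TAD in place of siCtrl, the median was -0.012 for cardiac transcription factors, within the random lists at percentile 50.42. The median was 0.96 for smooth muscle, 1.66 for matrix and -0.44 for cell cycle genes, all beyond the random lists on the other side. With GT/M2 in place of siCtrl it was 2.52, 1.91 and -2.37 for the last 3, also on the other side, and 0.27 for sarcomere genes, then above. Over the genes lower on GT/M2TAD than on MEF, the siEp300 minus siCtrl median was 0.15 with a 1.5-fold rule, 0.14 with no floor, 0.16 against unmatched sets and -0.028 after quantile normalization, each then below the random sets.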

Other observations

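The tests reported here were chosen after their results had been seen, except level-dependent centring of the genes higher on GT/M2TAD than on GT/M2, which was written down before that result. Histone genes with symbols beginning H1f, H2ac, H2bc, H3c or H4c, a set chosen after its values were seen, were lower as a group with every Mef2c form than on the MEF array. Of 57 measured, 45 were at least 2-fold lower on GT/M1, 45 on GT/M2, 46 on GT/M6 and 48 on GT/M2TAD, with medians of -2.76, -2.30, -2.95 and -3.87. They were also lower on GT/M2TAD than on GT/M2, at a median of -1.36 with 38 genes at least 2-fold lower. On siEp300 their median was 0.53 higher than on siCtrl with 12 at least 2-fold higher, and 0.33, 0.36 and 0.34 after quantile normalization, median centring and level-dependent centring.

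Chromatin-modifying enzymes of the acetyltransferase and deacetylase list went both ways on GT/M2TAD against MEF. The deacetylase Hdac6 was 4.33 higher, the coactivator Ncoa1 3.04, the acetyltransferase Kat2b 2.48 and Hdac9 2.05, while Kat7 was at -1.21, Hdac2 at -1.15 and Hdac7 at -1.08. Interferon response genes, 0.64 higher on siEp300 than on siCtrl, had a median of 0.46 and a percentile of 100 after level-dependent centring, and the macrophage list a median of -0.068, within the random lists. These values were looked at after the interferon result was seen.

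More genes were at least 2-fold higher than lower on siEp300 against siCtrl, 377 against 76. With the floor at the 95th percentile of negative-control probes, 117 genes were higher and 6 lower, so 95.1% of calls were higher. This argues against genes near background as the only source. Most of the 377 and 76 calls did not reach that floor. A shift between the arrays cannot be told apart from a difference in many transcripts by level-dependent centring, after which 50.8% of calls were higher, since centring removes a shift of either kind. Negative-control probes, which target no transcript, differed the same way by less, at a median of 0.088 against 0.16 expected from genes of their signal, and the median gap of -0.045 (95% interval -0.079 to -0.0083) leaves open how much of the shift they share. A true difference in many transcripts with Ep300 siRNA stays open, as does a difference in processing between the arrays.

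The siCtrl array stood apart from GT/M2TAD, with 1837 genes at least 2-fold apart, and 1599, 1634 and 1598 after quantile normalization, median centring and level-dependent centring. Over the 1228 genes 2-fold apart between GT/M2TAD and GT/M2, siCtrl lay at a median position of 1.14, where 0 is GT/M2 and 1 is GT/M2TAD. It was 0.93 over the genes higher on GT/M2TAD and 1.28 over the lower ones. This cannot decide the construct: the genes were chosen on the same GT/M2 array, so noise on that array alone moves siCtrl away from 0. No position of GT/M1 or GT/M6 was taken for reference. A larger share of cells dividing like untreated MEFs is argued against by the cell cycle genes, at a median of -0.95, while matrix genes at a median of 1.78 and Bcat1 at 4.4, both high on the MEF array, went the other way and leave fibroblasts that divide less open. Whether the siRNA arrays were processed as a set of their own stays open. Negative-control probes differed between the sets 1.05 times as much as within the more variable set, the siRNA pair. The SD was 1.30 between sets, 1.24 within that pair and 1.03 within the 4 construct arrays. The thr spike-in, which does not come from the cells, was 8.23 on siEp300, 8.42 on siCtrl and 7.02 to 7.54 on the other arrays. The lys, bioB and bioC spike-ins were also higher on both siRNA arrays than on any other array, by less. They were 6.24, 8.98 and 10.55 on siEp300 and 6.67, 8.98 and 10.61 on siCtrl, against at most 6.21, 8.84 and 10.51. The cre spike-in was lower, at 12.96 and 12.90 against at least 13.07. The dap, phe and bioD spike-ins did not set both siRNA arrays apart. The siRNA treatment itself was not tested as a source and stays open, and no construct was assigned to these arrays from their values.

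Genes higher on GT/M2TAD than on GT/M2 were lower on siEp300, relative to matched genes, and genes lower on GT/M2TAD were higher. At least 2-fold lower on GT/M2TAD were 22 of 29 cell cycle genes and 38 of 57 histone genes. The medians of these groups were 0.52 and 0.53 higher on siEp300 than on siCtrl, and their part in the result was not tested. A shift that depends on signal level is argued against by the random sets, which were matched on signal and carry such a shift. The median of the 578 higher genes lay below them. After centring it was -0.098, again below, but centring moves these genes and the random sets nearly alike. It could therefore hardly change the call. Whether siEp300 held fewer transduced cells stays open. The genes higher on GT/M2TAD than on MEF, with a median of 0.23, above the random sets, went against it. That set cannot tell the factors from infection or time in culture. Cell cycle and histone genes, lower with every Mef2c form than on MEF, were higher on siEp300 and went with it, as did the lower Mef2c signal. Dependence on Ep300 of the genes apart between GT/M2TAD and GT/M2 was not tested beyond this. It would need the siRNA cells to carry the MyoD domain, on which the labels disagree. A lower dose of the Mef2c construct was not tested and stays open: Mef2c was at -0.55 and Tbx5 at -0.0065 on siEp300 against siCtrl.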
